A study of Homo sapiens with 16 samples.

How the data were processed

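RNA was measured by sequencing in 16 libraries, 8 from the PC9 lung cancer line and 8 from the MDA231 breast cancer line. Per the labels' protocols, cells were lysed after culture in dishes, polyadenylated RNA was selected, and libraries were made with a stranded TruSeq kit. The labels place each library in 1 of 4 groups per line, with 2 libraries per group: parental cells with no hairpin, and LeptoM cells (a derivative that metastasises to the leptomeninges, the membranes around the brain) carrying a control hairpin (shCTL), shLCN2_1 or shLCN2_2. Both LCN2 hairpins were delivered by lentivirus, per the labels' protocols. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

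The authors deposited 1 table per cell line, and its values are a gene-level signal, namely gene reads divided by a size factor for each library. HTSeq 0.5.3, DESeq2 1.22.1 and the genome build hg19 are named in the submitters' processing notes. The aligner, the gene annotation and HTSeq's strand setting were not given in the sources used here, so antisense genes are reported as uncertain. The lines were normalized separately, and every test was run within a table. Each of the 155632 PC9 values and 143632 MDA231 values was within 0.001 of a whole number of reads once divided by the value of 1 read in its library, which gave 100% whole reads in both tables. The lowest genes kept had 15 reads over the 8 libraries of a table. The PC9 table also held 4 lines that name no gene. They took 24.4 to 36.5% of the reads of a library and were left out. In the parental replicate 2 library of PC9, reads aligned to more than 1 place amounted to 42.4% of the gene reads, against 18.1 to 20.6% in the other 7. SLC22A17, a receptor for the protein made from LCN2, was not analysed here.

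A gene at 3 reads in a library, the floor used here, has a value of 2.41 to 3.52 in PC9, 1.93 to 2.28 in the MDA231 LeptoM libraries and 8.51 to 8.94 in the MDA231 parental libraries. Reads copied by PCR are not independent molecules, so floors and counting intervals cover counting error only. Replicates were compared by a chi-square test of their reads, and the statistic per degree of freedom was 3.09 (PC9 LeptoM shCTL) to 43.5 (PC9 shLCN2_1), so no pair looked like a single library deposited again.

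The tests, gene lists, rule for named genes and alternatives were fixed before the data were examined, except where stated. Genes with a mean value of at least 10 were tested, 15650 in PC9 and 14387 in MDA231. Values were transformed as log2(value + 1), so fold changes of low genes depend on the 1 that was added and can be too small or too large. List medians that members with a group under the floor moved are also given with those groups set to the floor, a step chosen after seeing the data. Limma 3.58.1 (R 4.3.3) was fitted to the 4 groups of a table with a trended prior (4 residual degrees of freedom, 4.12 prior degrees of freedom in PC9 and 3.04 in MDA231), and p-values were two-sided and adjusted by Benjamini-Hochberg. A gene was called at an adjusted p under 0.05. The contrasts were LeptoM shCTL against parental, each hairpin against shCTL, the mean of the hairpins against shCTL, and shLCN2_1 against shLCN2_2. LCN2 in MDA231 lay under the minimum mean and was added to the genes of a separate fit. Statements of fold change in the text are log2 values with the standard error (SE) from limma unless another unit is given.

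The genes named are LCN2 in each comparison where it could be tested, the highest and lowest called genes of each contrast with a group mean of at least 50 and no overlap between libraries, and up to 4 called members of each gene list. Genes called in the same direction with both hairpins, or in both lines, were ranked by the smaller of the 2 fold changes. Y-linked genes were left out, and some genes that meet the rule are not reported here. Where fewer genes than the rule allows are named, they are examples, and any gene outside it is said to have been chosen after its values were seen.

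There were 20 gene lists: iron handling, mitochondrial respiration and iron-sulfur proteins, hypoxia response, NF-kB inflammatory genes, interferon-stimulated genes, complement, antigen presentation, cell cycle, epithelial genes, mesenchymal genes, cholesterol synthesis, ATF4 amino acid response, unfolded protein response, NRF2 antioxidant genes, MAPK pathway output genes, p53 target genes, macrophage and granulocyte markers, meningeal and choroid plexus markers, mitochondrially encoded transcripts and ribosomal protein genes. Each was tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of a line and contrast, and again with an estimated correlation. Differences between the lines were tested from the 2 fitted effects and their standard errors, by gene with Benjamini-Hochberg adjustment and by list with cameraPR.

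The alternatives were pseudocounts of 0.25 and 8, no minimum mean, a minimum of 50, upper-quartile and TMM scaling, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, limma's robust option, a fit of only the groups compared, the replicate number as a block, a log2 fold change of at least 1, the estimated correlation, and each library left out in turn. When a library was left out, its partner was assumed to vary like the other groups. Chosen after seeing the data were a fit with the trend of each library's values along gene GC content removed, the same fit with the replicate block, and reads thinned to the depth of the shallowest library. GC content came from the GENCODE v29 annotation of GRCh38 and was found for 97.6% of the tested PC9 genes and 97.9% of the MDA231 genes. Overlaps and correlations of contrasts that share the shCTL libraries are given with values from 100 simulations of unchanged groups. All 8 libraries of a table were simulated, the shCTL libraries included. With no group changed almost no gene is called, so the simulated overlaps do not show how much the shared controls add. The simulated correlations are set by the shared libraries alone. They are no reference for observed correlations, which also hold changes between groups, so the covariances are the closer comparison.

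The steps were tested on simulated data with 200 genes changed. For PC9 LeptoM shCTL against parental, limma recovered 44.8% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 97.0% of those changed 4-fold, and called 10 of 15420 unchanged genes. The shares for PC9 shLCN2_1 were 41.8%, 82.1% and 95.5% (10 unchanged genes called), and for PC9 shLCN2_2 53.7%, 86.6% and 97.0% (12 called). In MDA231 they were 25.4%, 73.1% and 95.5% against parental (25 of 14157 unchanged genes called), 38.8%, 79.1% and 97.0% with shLCN2_1 (5 called) and 22.4%, 79.1% and 95.5% with shLCN2_2 (4 called). A list of 30 genes changed 1.5-fold was found in each of these comparisons, and 0 of 20 unchanged lists were called. The simulated genes varied independently and the lists were drawn at random. The list test was therefore not tried on genes that vary together, where the preset correlation matters. For the gene test all groups were simulated with a common spread and no GC trend. The numbers of unchanged genes called need not hold for the libraries studied here. Other software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.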

Results

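Gene expression was measured in 16 RNA-seq libraries from PC9 lung cancer cells and MDA231 breast cancer cells. Each line was represented by parental cells, LeptoM cells with a control hairpin (shCTL) and LeptoM cells with either of 2 hairpins against LCN2 (shLCN2_1 and shLCN2_2), with 2 libraries per group. LCN2 encodes lipocalin-2, a secreted protein that binds the siderophores with which bacteria capture iron. The design asks how LeptoM cells differ from the parental cells, and what changes in LeptoM cells when LCN2 is lowered. Depth ranged from 36796098 to 51759154 gene reads in PC9 and from 41751486 to 49050069 in the MDA231 LeptoM libraries. The MDA231 parental libraries held 11592790 and 11613984. The plot of fold change by GC content shows a property of the libraries that bears on the comparisons. Both PC9 shLCN2_1 libraries had lower values for genes of high GC content than the other PC9 libraries. The Spearman correlation across genes between GC content and the deviation from the mean of the table was -0.548 and -0.645, against -0.168 to 0.529 in the other 6. In MDA231 it ran from -0.592 (parental replicate 2) to 0.646 (shLCN2_2 replicate 1). The 2 replicates of each MDA231 group also differed along GC content, replicate 1 minus replicate 2 having a Spearman correlation with it of 0.638 in parental cells, 0.625 with shCTL, -0.681 with shLCN2_1 and 0.674 with shLCN2_2. In PC9 these values were -0.516, 0.287, 0.0951 and -0.223. Since the PC9 shLCN2_1 libraries share their trend, a technical origin cannot be told apart from an effect of that hairpin. Removing the trend may therefore remove real change as well. Genes are not independent replicates.

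LCN2 (ENSG00000148346.7, chromosome 9, positions 128149071 to 128153455 on the plus strand in GRCh38) was abundant in PC9. Its normalized read count was 22194 ± 1490 (SD, n = 2) in parental cells and 50310 ± 982 (n = 2) in LeptoM shCTL cells, a rise of 1.18 on the log2 scale (SE 0.25, adjusted p = 0.00641). It fell by 3.33 with shLCN2_1, to 5311 ± 2455 (adjusted p = 0.000167), and by 1.32 with shLCN2_2, to 20138 ± 1806 (adjusted p = 0.0111). LCN2 was lower with shLCN2_1 than with shLCN2_2 by a log2 difference of -2.00 (adjusted p = 0.00035). The shLCN2_1 replicates held 3575 and 7046, the shLCN2_2 replicates 21415 and 18861, and the 2 shCTL replicates 51004 and 49615. The shLCN2_2 call was lost without either shLCN2_2 library or either shCTL library, where the log2 fold change was -1.42 to -1.23. Such fits leave 1 library in a group, and their shared spread includes the shLCN2_1 replicates. Limma fitted to only the shLCN2_2 and shCTL groups gave -1.32 (adjusted p = 9.8e-14). That fit leaves 2 residual degrees of freedom, so its p-value rests largely on spread borrowed from other genes. It called 8045 genes with shLCN2_2, beside 3053 with all 4 groups fitted, and does not make the LCN2 call firmer. In MDA231, LCN2 was close to the limit of detection, with 4 reads over both parental libraries, 45 over the shCTL libraries, 19 with shLCN2_1 and 13 with shLCN2_2. The normalized read counts were 5.74 ± 3.91 (n = 2) in parental cells, 16.5 ± 3.999 with shCTL, 6.16 ± 0.530 with shLCN2_1 and 4.62 ± 0.437 with shLCN2_2. The parental level lies at or under the value of 3 reads in those libraries (8.51 and 8.94). For the difference from shCTL the adjusted p was 0.0364. It rose to 0.0601 to 0.189 with any 1 of 7 of the 8 libraries left out, fell to 0.0021 without parental replicate 1, and was 0.508 with reads thinned to equal depth. The falls with shLCN2_1 and shLCN2_2 did not pass the test in MDA231 (adjusted p = 0.299 and 0.226), although without either parental library that with shLCN2_2 did (0.0393 and 0.0391).

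**Figure D1:**
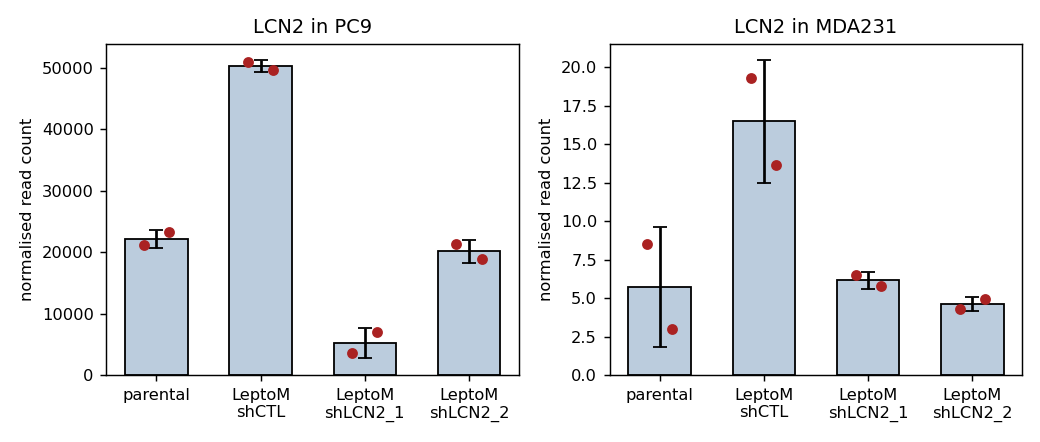
Normalized LCN2 read count (y axis) by group (x axis) in PC9 and MDA231 cells; bars are means, error bars SD and points the 2 libraries of each group. The PC9 means were 22194 in parental cells, 50310 with shCTL, 5311 with shLCN2_1 and 20138 with shLCN2_2, and in MDA231 no group mean exceeded 16.5.

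In PC9 LeptoM shCTL cells SLC6A14, an amino acid transporter, rose by 8.19 on the log2 scale over parental cells (SE 0.40) and the carcinoembryonic antigen gene CEACAM5 by 7.78 (SE 0.19). The aldehyde dehydrogenase gene ALDH3A1 rose by 7.63 (SE 0.16, 96.8 to 19258) and the airway mucin gene MUC5B by 6.71 (SE 0.46). A further 4 genes had 1 to 3 reads over both parental libraries and high levels in LeptoM cells: SELENBP1 (1.08 to 489), ADCY5 (1.67 to 423), GGT6 (0.496 to 171) and CYP4F12 (0.587 to 156). The intermediate filament gene VIM fell (-4.31, SE 0.28), as did the actin-bundling gene LCP1 (-5.49, SE 0.17) and PLAC8 (-5.24, SE 0.52). The chromatin gene CDYL2 (-5.53, SE 0.42) and the collagen gene COL5A1 (-5.53, SE 0.78) fell as far. ACSS3, with 0 reads in LeptoM shCTL cells, was at least 19.5-fold lower and the non-coding LINC00052 at least 17.3-fold lower, both against 3 reads per library, and TSHZ3 went from 199 to 0.967.

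Among the gene lists, 9 of 20 moved in PC9 LeptoM cells. NRF2 antioxidant genes rose, with 19 of 23 higher and 0 lower (21 and 0 adjusted over the list alone, median 0.75, camera adjusted p = 3.45e-10). Theirs was the only list still called with an estimated correlation (adjusted p = 0.0349 with an estimated correlation). They included the aldo-keto reductases AKR1B10 (3.52, SE 0.06) and AKR1C1 (3.17, SE 0.09), the glutathione peroxidase GPX2 (2.17, SE 0.07) and OSGIN1 (1.51, SE 0.19). Epithelial genes rose (16 higher and 3 lower of 24, 17 and 3 adjusted over the list alone). Their median was 0.41 (adjusted p = 0.00635), and they included ELF3 (2.17) and MUC1 (1.63). Mesenchymal genes fell (2 higher and 10 lower of 18, 2 and 12 adjusted over the list alone). Their median was -1.27 (adjusted p = 0.0164), and they included VIM, TNC (-3.03, SE 0.76) and the fibronectin gene FN1 (-2.89, SE 0.50). For both of these lists the adjusted p = 0.463 with an estimated correlation. Ribosomal protein genes rose (23 higher and 0 lower of 30, 27 and 0 adjusted over the list alone). Their median was 0.34 (adjusted p = 2.06e-06, 0.463 with an estimated correlation), with RPS27 at 0.71 and RPL13 at 0.62 (0.38 with the GC trend removed). Hypoxia response genes fell (4 higher and 18 lower of 33, 5 and 18 adjusted over the list alone). Their median was -0.37 (adjusted p = 0.000707), and they included the glucose transporter SLC2A3 (-3.82), the carbonic anhydrase CA9 (-1.70) and BNIP3 (-1.23). Cell cycle genes fell as well (1 higher and 17 lower of 34, the same adjusted over the list alone, median -0.28, adjusted p = 0.00047). They were led by the thymidylate synthase gene TYMS (-1.61), with the mitotic kinase genes AURKA (-0.67) and BUB1 (-0.65). The hypoxia and cell cycle lists each had an adjusted p = 0.463 with an estimated correlation.

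Cholesterol synthesis genes rose in PC9 LeptoM cells (8 higher and 0 lower of 25, the same adjusted over the list alone, median 0.42, adjusted p = 0.0108, 0.691 with an estimated correlation). They included the sterol reductase TM7SF2 (1.96) and the regulator SREBF2 (0.79). ATF4 amino acid response genes rose (10 higher and 3 lower of 21, 12 and 3 adjusted over the list alone). Their median was 0.52 (adjusted p = 0.0199, 0.463 with an estimated correlation), with ATF3 at 2.20, CHAC1 at 2.13 and the asparagine synthetase gene ASNS at 1.21. The adjusted p of the list was 0.052 with the GC trend removed. Of 7 measured meningeal and choroid plexus markers, 5 rose and 0 fell (the same adjusted over the list alone). Their median was 1.32 (adjusted p = 0.0263, 0.463 with an estimated correlation), and levels were low. SLC6A13 went from 2.84 to 17.7, the retinaldehyde dehydrogenase gene ALDH1A2 from 4.42 to 26.2 and the water channel gene AQP1 from 8.76 to 31.9. Iron handling genes did not move as a list (6 higher and 7 lower of 25, 7 and 7 adjusted over the list alone, adjusted p = 0.997), but members moved both ways. The metalloreductases STEAP4 (3.15) and CYBRD1 (1.45) and the iron exporter SLC40A1 (1.35) rose, and ACO1, which encodes an iron-sensing aconitase, fell by 2.11. Of macrophage and granulocyte markers, S100A8 (5.06) and CD14 (2.14) rose, with 4 higher and 1 lower of 7 (adjusted p = 0.0815). Lists with no call were mitochondrial respiration and iron-sulfur proteins (8 higher and 9 lower), NF-kB inflammatory genes (3 and 3), interferon-stimulated genes (14 and 4), complement (7 and 3) and antigen presentation (4 and 9). No call was made either for the unfolded protein response (4 and 8), MAPK output (5 and 5), p53 targets (8 and 4) and mitochondrially encoded transcripts (2 and 2), with adjusted p from 0.109 to 1. For respiration (median 0.05) and NF-kB genes (0.01) the median and the direction of the test differ in sign.

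Across all tested genes, limma called 3720 higher and 3418 lower of 15650 in PC9 LeptoM shCTL against parental cells, and 1476 and 622 of these differed by a log2 fold change of at least 1. LeptoM shCTL cells also differ from parental cells in carrying a hairpin vector, which this comparison cannot separate from the derivation. The count fell to 4161 without shCTL replicate 1 and 4360 without shCTL replicate 2. TNC and IGFN1 lost their calls without any 1 of the 4 libraries compared, and SLC6A13 without shCTL replicate 1 (adjusted p up to 0.0637). The mesenchymal list was not called without parental replicate 2 (0.0663) and the meningeal list without either shLCN2_1 library (0.0517 and 0.0516).

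In MDA231, KALRN had 0 reads in parental cells and was at least 47.1-fold higher in LeptoM shCTL cells, the interferon-induced chemokine CXCL11 at least 20.1-fold and the cancer-testis gene MAGEA12 at least 19.1-fold higher, each against 3 reads per library. The cystatin gene CST1 rose by 7.10 (SE 0.47), and the cancer-testis gene SSX1 by 7.03 (SE 0.28). The receptor gene GPR176, with 5 reads over both parental libraries, went from 7.45 to 846, and MAGEA6, with 3 reads, from 4.47 to 727. The matrix glycoprotein gene SPARC fell by 9.17 (SE 0.33) and PAGE5, another cancer-testis gene, by 9.07 (SE 0.26). TUBA3C was at least 922-fold lower, MFHAS1 at least 198-fold and CSMD1 at least 103-fold lower, TMEM47 went from 548 to 0.715 and PLCB4 from 437 to 0.358. MAGEA6, MAGEA12, SSX1 and TUBA3C share reads with near-identical copies, and SLC7A11-AS1 (-8.30, SE 0.53) is antisense, so those values are uncertain.

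Mitochondrially encoded transcripts rose in MDA231 LeptoM cells (10 higher and 0 lower of 13, 11 and 0 adjusted over the list alone, median 0.79, adjusted p = 0.000955, 0.525 with an estimated correlation). Among them MT-ND5 stood at 1.42 (SE 0.12), MT-ND4 at 0.98 and MT-CO1 at 0.94. They made up 0.839 and 0.944% of gene reads in the parental libraries and 1.34 to 1.93% in the LeptoM libraries. Nuclear genes for mitochondrial respiration and iron-sulfur proteins fell (4 higher and 14 lower of 33, 4 and 16 adjusted over the list alone). Their median was -0.31 (adjusted p = 0.0244), and they included COX7B of cytochrome oxidase (-1.53), while SDHA of complex II rose by 1.15. Interferon-stimulated genes rose (18 higher and 2 lower of 31, the same adjusted over the list alone). Their median was 0.70 (0.65 with groups under 3 reads per library set to 3 reads, adjusted p = 0.00635), with OASL at 2.91, IFITM1 at 2.62 and IFIT2 at 2.10, whereas BST2 fell by 3.80. Ribosomal protein genes fell (1 higher and 15 lower of 30, the same adjusted over the list alone). Their median was -0.33 (adjusted p = 0.00635), with RPL32 at -1.09 and RPS18 at -0.89 against RPL37 at 0.81. For the respiration, interferon and ribosomal lists the adjusted p = 0.482 with an estimated correlation.

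Epithelial genes rose in MDA231 LeptoM cells (6 higher and 0 lower of 14, the same adjusted over the list alone, median 0.44, or 0.24 with groups under 3 reads per library set to 3 reads, adjusted p = 0.0211, 0.482 with an estimated correlation), including plakoglobin (JUP, 3.11), CLDN4 (2.89) and KRT19 (2.37). Genes of high GC content were higher in the shCTL than in the parental libraries (Spearman correlation 0.417 across genes, median -0.28 in the lowest of 5 bins of GC content and 0.60 in the highest). After removal of this trend the epithelial list had an adjusted p of 0.14. All 3 measured meningeal markers rose (3 adjusted over the list alone). Their median was 1.39 (0.71 with groups under 3 reads per library set to 3 reads, adjusted p = 0.0492, 0.482 with an estimated correlation). CLIC6 rose by 1.39, and FOLR1, with 0 parental reads, was at least 1.64-fold higher. This call was lost with the GC trend removed (adjusted p = 0.20) and without shCTL replicate 2 (0.0538), parental replicate 1 (0.0866) or any 1 hairpin library (0.0511 to 0.0541). Single members of lists that did not move as a whole also changed. The chemokine CCL2 rose by 5.05 (SE 0.14) and the adhesion gene ICAM1 by 2.24 (NF-kB list, 11 higher and 9 lower of 28). S100A4 rose by 3.63 and COL6A1 by 2.94 (mesenchymal, 10 and 2 of 19, adjusted p = 0.0669). EREG rose by 3.17 and DUSP6 by 1.57 (MAPK output, 10 and 2 of 20, adjusted p = 0.0624) and HLA-B by 1.63 (antigen presentation, 12 and 3 of 22, adjusted p = 0.0624). The quinone reductase NQO1 fell by 1.68 (NRF2 list, 4 and 5), the serine synthesis gene PSAT1 by 1.51 (ATF4 list, 4 and 9), and the ferritin gene FTH1 rose by 0.70 (iron handling, 3 and 7). Lists with no call also included hypoxia (5 and 9), complement (5 and 4), cell cycle (4 and 10), cholesterol synthesis (4 and 11), the unfolded protein response (1 and 5), p53 targets (5 and 7) and macrophage and granulocyte markers (2 and 0).

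Limma called 3572 genes higher and 3429 lower of 14387 in MDA231 LeptoM shCTL against parental cells, 1709 and 684 of them with a log2 fold change of at least 1. Both parental libraries held 11.6 M gene reads and the shallowest LeptoM library 41.8 M, so a separate batch cannot be told apart from the group. Here too the LeptoM cells carry a hairpin vector that the parental cells lack. None of the alternative fits can separate these from the derivation. Upper-quartile scaling moved the median of all genes from 0.04 to 0.12. Without shCTL replicate 1 or replicate 2 the count was 3486 or 4447; LCN2 aside, the 51 genes named for this comparison kept their calls with any library left out, with the GC trend removed and with reads thinned to equal depth.

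Across the lines, RNF43, a negative regulator of Wnt receptors, rose by 3.53 in PC9 and from 7.305 to 141 in MDA231, the secretory pathway gene AGR2 by 3.002 and 4.63. The laminin gene LAMA4 rose by 3.72 and 3.67, FAM49A by 4.001 and 3.01, and the interferon-stimulated gene OASL by 2.99 and 2.91. SELENBP1 rose in both lines, from 5.89 to 81.2 in MDA231. The dystrophin gene DMD fell in both (-3.77 and -5.76), as did the adaptor gene PIK3AP1 (-3.93 and -2.13) and the focal adhesion gene TNS1 (-2.01 and -2.17). IGFN1 (-2.62 and -3.63) and the ciliary gene CC2D2A (-3.02 and -2.06) fell too. Other genes differed between the lines when the difference itself was tested. They were VIM (-4.31 in PC9 and 0.21 in MDA231, adjusted p of the difference 0.000131), ICAM1 (-1.09 and 2.24, 7.22e-05) and HLA-B (-1.59 and 1.63, 0.000258). Also among them were NQO1 (1.07 and -1.68, 6.09e-05), ASNS (1.21 and -1.46, 0.00013) and CYBRD1 (1.45 and -0.72, 0.000204). Of 13388 genes tested in both lines, 850 were called higher in both and 1016 lower in both, where independent lists would share 696.8 and 784.1 (Fisher's exact test, two-sided, p = 1.35e-13 and 9.77e-27). A further 590 were higher in PC9 and lower in MDA231 (703.1 for independent lists) and 796 the reverse (777.1). Across genes, which are not independent replicates, the fold changes of the lines had a Pearson correlation of 0.119 (Spearman 0.138). With the GC trend removed 944 were higher and 1278 lower in both, beside 883.3 and 1120 for independent lists, and the Pearson correlation was 0.0732. It was 0.0786 without PC9 parental replicate 1. Left out one at a time, the libraries moved the number shared from 1866 to between 924 and 2467.

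**Figure D2:**
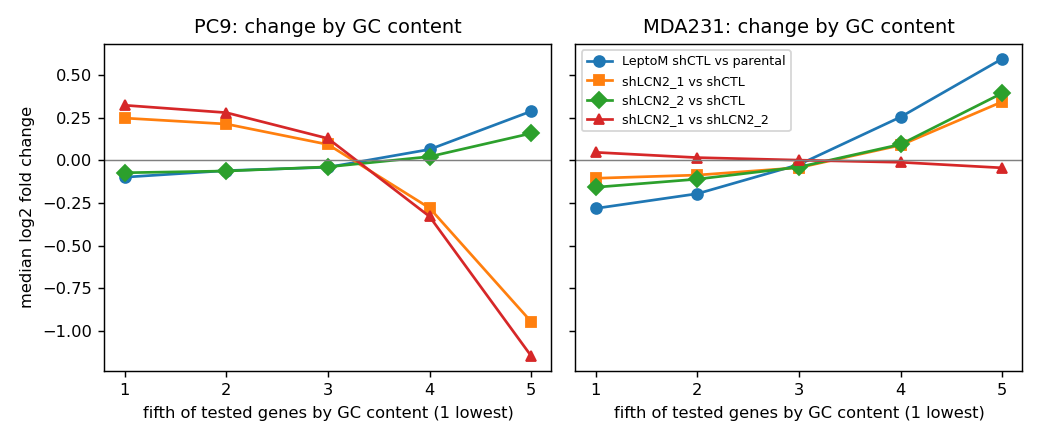
Median log2 fold change (y axis) of the tested genes in each of 5 equal bins of gene GC content (x axis, lowest to highest) for LeptoM shCTL against parental, each hairpin against shCTL, and shLCN2_1 against shLCN2_2, in PC9 and MDA231. With shLCN2_1 the PC9 medians ran from 0.25 in the lowest bin to -0.95 in the highest, and with shLCN2_2 in MDA231 from -0.16 to 0.39.

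In PC9 LeptoM cells, a shared set of genes rose with both hairpins against LCN2. The scaffold gene DISC1 rose by 2.40 with shLCN2_1 (SE 0.23) and 2.14 with shLCN2_2 (SE 0.23), and the endocytic receptor LY75 by 2.18 and 2.09. The insulin-like gene INSL4 rose by 2.09 and 1.78, FAM184A by 2.03 and 1.94, and HPCAL4 by 1.97 and 1.82. ARHGAP31 rose by 1.95 and 2.99, the R-spondin receptor LGR6 by 1.83 and 2.74, and the airway secretory gene BPIFA1 by 2.24 and 2.55. Interleukin-6 (IL6) fell by 1.33 and 1.98, the tyrosine catabolism gene HPD by 1.26 and 2.53, and the collagen gene COL8A1 by 1.29 and 1.46. PADI3 fell by 1.04 and 1.12, and SH2D5 by 1.03 and 1.18. The uridine phosphorylase gene UPP1 fell by 0.92 and 0.93, and AC002480.3 was lower with both (-1.0003 and -1.04). After removal of the GC trend the shLCN2_1 value of UPP1 was -0.29, those of HPD (-0.83) and PADI3 (-0.71) were not called, and that of SH2D5 turned to 0.38 (adjusted p = 0.233). In total 522 genes were called higher and 325 lower with both hairpins, beside 288.8 and 384.7 for independent lists. Simulations in which no group changed gave a mean of 0.04, which does not measure what the shared controls add. The 2 control libraries were not split between the hairpins, so part of the excess among the higher genes may come from the shared controls. Another 636 genes were called in opposite directions, 256 higher with shLCN2_1 and 380 higher with shLCN2_2 (285.6 and 389.0 for independent lists), and with the GC trend removed there were 668 and 496 called alike and 242 called oppositely. The numbers alike were 119 to 149 without either shCTL library and 126 and 207 without either shLCN2_2 library, and rose to 1690 and 1539 without either shLCN2_1 library.

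With shLCN2_1 in PC9, interferon-stimulated genes rose (17 higher and 4 lower of 31, 18 and 4 adjusted over the list alone). Their median was 0.55 (adjusted p = 0.0038, 0.639 with an estimated correlation), with XAF1 at 1.68 (SE 0.33) and OAS2 at 1.99 (SE 0.57). ISG15 (-1.78) and IRF7 (-1.86) were lower only in the fit that kept the GC trend (-0.55 and -0.32 without it, not called). NF-kB inflammatory genes fell (0 higher and 10 lower of 26, the same adjusted over the list alone). Their median was -1.08 (adjusted p = 0.00201, 0.639 with an estimated correlation), and they included TNFAIP2 (-1.29), IL6 and RELB (-1.40). Without shLCN2_1 replicate 1 the median was -0.25 (adjusted p = 0.107), and with the GC trend removed it was -0.56 (0.00064) with RELB at -0.05 and TNFAIP2 at -0.45. Ribosomal protein genes fell (0 higher and 18 lower of 30, 0 and 19 adjusted over the list alone). Their median was -0.25 (adjusted p = 0.00201, 0.639 with an estimated correlation), with RPLP1 at -1.56 and RPL8 at -1.10 (-0.24 with the GC trend removed). Epithelial genes were lower (4 higher and 14 lower of 24, 4 and 15 adjusted over the list alone, median -0.49, adjusted p = 0.00954, 0.639 with an estimated correlation), with KRT19 at -1.29 and the plakophilin PKP3 at -1.93. MAPK output genes were lower (1 and 10 of 20, 1 and 11 adjusted over the list alone, median -0.42, adjusted p = 0.0268, 0.639 with an estimated correlation), with EPHA2 at -0.95. Mitochondrially encoded transcripts were higher (5 and 0 of 13, 8 and 0 adjusted over the list alone, median 0.28, adjusted p = 0.00954, 0.639 with an estimated correlation), with MT-ND3 at 0.51 and MT-CYB at 0.34. The last 3 lists moved with the GC trend of the shLCN2_1 libraries (Spearman correlation -0.663 across genes between fold change and GC content). Without it their adjusted p was 0.40, 0.86 and 0.64, PKP3 stood at -0.08, KRT19 at -0.58, EPHA2 at 0.09, MT-ND3 at 0.26 and MT-CYB at 0.15. The complement gene CFD (-1.29) and the meningeal transcription factor FOXC1 (-0.31) likewise stood at 0.40 and 0.02 with the trend removed. Without shLCN2_1 replicate 1 the MAPK and mitochondrially encoded lists were not called (0.0930 and 0.107), nor was the epithelial list without replicate 2 (0.0506). The complex I gene NDUFS7 fell by 2.81 (-1.36 with the trend removed), and the iron genes CYBRD1 and SLC40A1 rose by 0.93 and 0.74.

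Other lists were not called with shLCN2_1: iron handling (6 higher and 5 lower), respiration (10 and 10), hypoxia (9 and 11), complement (3 and 1), antigen presentation (3 and 8), cell cycle (1 and 10) and mesenchymal (3 and 5). The same held for cholesterol (8 and 5), ATF4 (3 and 10), unfolded protein response (7 and 7), NRF2 (4 and 9), p53 (8 and 7), macrophage (0 and 4) and meningeal (1 and 2). Over all genes limma called 2944 higher and 3966 lower, a share of 42.6% higher that became 56.0% with upper-quartile scaling (4409 and 3465), 52.2% with TMM (3972 and 3636) and 52.9% with edgeR (4071 and 3623). Upper-quartile scaling moved the median of all genes from 0.03 to 0.13. With the GC trend removed 1882 were higher and 1875 lower, and 2372 of the 6910 calls were kept while 296 were called in the opposite direction. The count fell to 3866 without shCTL replicate 1 and 4370 without shCTL replicate 2. BPIFA1, HPD, COL8A1, PADI3, OAS2, MT-CYB, CFD, FOXC1 and AC002480.3 lost their calls without either shCTL library, COL8A1 and MT-CYB without shLCN2_1 replicate 1, and BPIFA1 and OAS2 without replicate 2 (adjusted p up to 0.124).

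With shLCN2_2 in PC9, interferon and antigen presentation genes rose together. Of 31 interferon-stimulated genes, 19 were higher and 0 lower (24 and 0 adjusted over the list alone, median 0.56, adjusted p = 6.58e-11, 0.0834 with an estimated correlation), with OAS2 at 3.36 (SE 0.57), IFI27 at 3.22 and IFI6 at 2.25. Complement genes rose (6 higher and 0 lower of 14, the same adjusted over the list alone). Their median was 0.50 (adjusted p = 0.00187), with the C1 inhibitor gene SERPING1 at 3.84 and C1R at 1.02. Antigen presentation genes rose (9 and 0 of 17, the same adjusted over the list alone). Their median was 0.38 (adjusted p = 0.00127), with CD74 at 2.65 and HLA-B at 1.63. Both lists had an adjusted p = 0.18 with an estimated correlation. NRF2 antioxidant genes fell (1 higher and 12 lower of 23, 1 and 17 adjusted over the list alone). Their median was -0.45 (adjusted p = 8.16e-08, 0.0672 with an estimated correlation), with AKR1C1 at -1.28, AKR1B10 at -1.13 and the cystine transporter SLC7A11 at -1.25. ATF4 response genes fell (2 and 9 of 21, 3 and 10 adjusted over the list alone). Their median was -0.40 (adjusted p = 0.000908, 0.244 with an estimated correlation), with ASNS at -0.81. Ribosomal protein genes fell (0 higher and 22 lower of 30, 0 and 25 adjusted over the list alone). Their median was -0.34 (adjusted p = 7.27e-12, 0.243 with an estimated correlation), with RPL7 at -0.55 and RPS27 at -0.50. Cell cycle genes fell (0 and 14 of 34, 0 and 22 adjusted over the list alone, median -0.27, adjusted p = 2.23e-08, 0.124 with an estimated correlation), with MCM7 at -0.42 and PLK1 at -0.39. Respiration genes fell (0 and 6 of 33, the same adjusted over the list alone, median -0.17, adjusted p = 0.00135, 0.216 with an estimated correlation), with SDHB at -0.39. Mesenchymal genes rose (3 and 0 of 18, the same adjusted over the list alone). Their median was 0.41 (adjusted p = 0.0375, 0.481 with an estimated correlation), with COL5A1 at 4.35 (SE 0.78) and MMP14 at 1.06. The list was not called with the GC trend removed (0.057), without either parental library (0.0608 and 0.0610), without shCTL replicate 1 (0.0648) or without shLCN2_2 replicate 2 (0.0526). The ferritin light chain gene FTL fell by 1.03 and CYBRD1 rose by 1.13.

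The remaining lists were not called with shLCN2_2: iron handling (2 higher and 5 lower), hypoxia (7 and 6), NF-kB (0 and 2), epithelial (6 and 2) and cholesterol (1 and 0). Nor were the unfolded protein response (2 and 5), MAPK (1 and 4), p53 (6 and 3), macrophage (2 and 0), meningeal (1 and 0) and mitochondrially encoded (2 and 0). Limma called 1535 genes higher and 1518 lower, and 361, 556, 505 and 367 in total without shLCN2_2 replicate 1, shLCN2_2 replicate 2, shCTL replicate 1 and shCTL replicate 2. Without any 1 of these 4 libraries LCN2, BPIFA1, COL8A1, PADI3, IFI27, PLK1, SDHB, COL5A1, MMP14 and AC002480.3 lost their calls, and OAS2, INSL4, MCM7 and SH2D5 without any of 3 of them. FAM184A and SERPING1 lost theirs without shLCN2_2 replicate 1 and RPS27 without shCTL replicate 2 (adjusted p up to 0.194 over these genes). Between the hairpins, 4006 genes were higher and 4523 lower with shLCN2_1, 193 and 2157 of them by a log2 fold change of at least 1. Most calls were higher instead with upper-quartile scaling (5033 and 4128), TMM (4716 and 4275) and edgeR (4861 and 4314). With the GC trend removed 5100 were called, and 3199 of the 8529 calls were kept while 512 were called in the opposite direction. NF-kB genes (1 higher and 11 lower of 26, the same adjusted over the list alone, median difference -0.91, adjusted p = 0.0141, 0.678 with an estimated correlation) were lower with shLCN2_1 than with shLCN2_2. So were antigen presentation genes (1 and 11 of 17, the same adjusted over the list alone, -0.87, adjusted p = 0.0117, 0.674 with an estimated correlation) and epithelial genes (2 and 15 of 24, 3 and 16 adjusted over the list alone, -0.60, adjusted p = 0.0117, 0.674 with an estimated correlation). These medians were -0.59, -0.30 and -0.13 with the GC trend removed (adjusted p = 0.0432, 0.0496 and 0.129). The calcium-binding gene CALB1 was higher with shLCN2_1 by 2.99, and COL5A1 (-4.96), AC005618.1 (-4.53) and the Wnt ligand gene WNT3A (-3.95; -2.17 with adjusted p = 0.0706 with the GC trend removed) were higher with shLCN2_2. Across genes the hairpins' fold changes had a Pearson correlation of 0.129 (Spearman 0.0744) and a covariance of 0.0404, beside 0.501 and 0.0260 simulated for unchanged groups with shared controls. Removing the GC trend gave 0.425 and 0.0910, beside 0.499 and 0.0232.

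For the mean of the hairpins in PC9, interferon-stimulated genes rose (17 higher and 0 lower of 31, 24 and 2 adjusted over the list alone). Their median was 0.58 (adjusted p = 4.12e-09, 0.116 with an estimated correlation), with OAS2 at 2.67, XAF1 at 1.80, MX2 at 1.52 and IFI6 at 1.37. Complement genes rose (4 and 0 of 14, the same adjusted over the list alone, median 0.29, adjusted p = 0.005, 0.278 with an estimated correlation), with SERPING1 at 3.27 and C1R at 0.59. NRF2 antioxidant genes fell (1 higher and 13 lower of 23, 1 and 16 adjusted over the list alone). Their median was -0.31 (adjusted p = 2.54e-05, 0.116 with an estimated correlation), and they included sulfiredoxin (SRXN1, -1.42) and OSGIN1 (-1.37; -0.90 with the GC trend removed). ATF4 response genes (2 and 10 of 21, the same adjusted over the list alone, median -0.30, adjusted p = 0.00228, 0.327 with an estimated correlation) fell with the amino acid transporters SLC7A5 (-1.17) and SLC3A2 (-0.75). Ribosomal protein genes fell (0 and 22 of 30, 0 and 26 adjusted over the list alone). Their median was -0.33 (adjusted p = 2.06e-10, 0.327 with an estimated correlation), with RPLP1 at -0.89. Cell cycle genes fell (0 and 12 of 34, 0 and 13 adjusted over the list alone). Their median was -0.15 (adjusted p = 6.1e-05, 0.278 with an estimated correlation), with MCM5 at -0.72 and PLK1 at -0.58 (-0.46 and -0.38 with the GC trend removed). NF-kB genes fell (0 and 5 of 26, the same adjusted over the list alone). Their median was -0.56 (adjusted p = 0.00512, 0.72 with an estimated correlation), with IL6 at -1.66, LIF at -0.89 and NFKB2 at -0.56. Without shLCN2_1 replicate 1 the NF-kB median was -0.20 (adjusted p = 0.142). MAPK output genes were lower (0 and 7 of 20, the same adjusted over the list alone, median -0.26, adjusted p = 0.0103, 0.327 with an estimated correlation), with EPHA2 at -0.55. Mitochondrially encoded transcripts were higher (4 and 0 of 13, 5 and 0 adjusted over the list alone, median 0.18, adjusted p = 0.00498, 0.72 with an estimated correlation), with MT-ND3 at 0.51. These 2 lists moved with GC content (Spearman correlation -0.448 across genes) and were not called with that trend removed (0.16 and 0.12), nor were NFKB2 (-0.14) and EPHA2 (-0.12). CYBRD1 rose by 1.03 and FTL fell by 0.68 within an iron handling list that was not called (4 and 2). The other lists without a call were respiration (0 and 9), hypoxia (6 and 9), antigen presentation (3 and 3), epithelial (4 and 11), mesenchymal (2 and 0), cholesterol (2 and 1), unfolded protein response (3 and 6), p53 (7 and 6), macrophage (0 and 0) and meningeal (1 and 1). A fit without 1 shCTL library leaves 1 control library and fewer degrees of freedom, so lost calls need not mean dependence on that library. The number of genes called was 1645 higher and 2727 lower. It was 120 without shCTL replicate 1 and 703 without shCTL replicate 2. Of the 25 genes named for this contrast 20 and 9 lost their calls (adjusted p up to 0.227 and 0.158), leaving IFI6, SERPING1, MCM5, LIF and CYBRD1 without replicate 1. CST4 and LEPREL1 were not called without either shLCN2_2 library, nor NQO1 without shLCN2_2 replicate 2 (up to 0.107). Upper-quartile scaling moved the share higher from 37.6 to 50.5%.

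**Figure D3:**
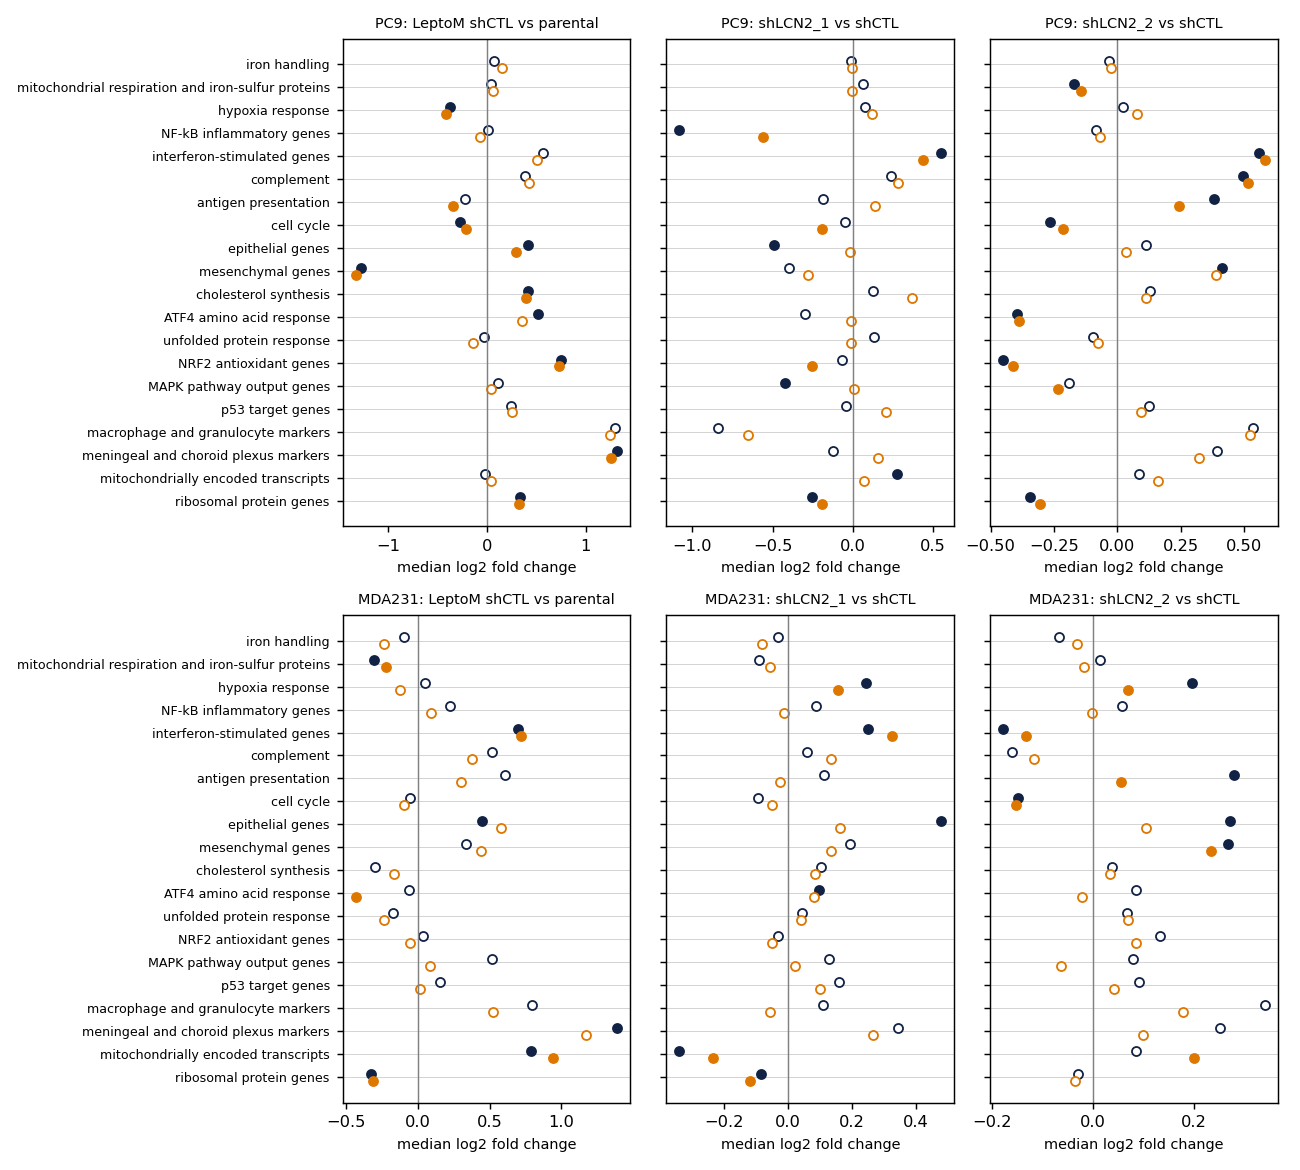
Median log2 fold change (x axis) of each gene list (y axis) for LeptoM shCTL against parental and each hairpin against shCTL, in PC9 and MDA231. Dark blue points are the fit as deposited and orange points the fit with the GC trend removed, filled where camera's adjusted p was under 0.05 and open where not. Interferon-stimulated genes stood at 0.55 with shLCN2_1 and 0.56 with shLCN2_2 in PC9, and at 0.25 and -0.18 in MDA231.

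In MDA231 LeptoM cells few genes passed limma's test when LCN2 was targeted, and the number depended on the tool and settings. With both hairpins the hypoxia-induced gene NDRG1 rose by 0.84 (SE 0.12) and 0.89 (SE 0.12), the fatty acid desaturase gene SCD by 0.83 and 1.12 and the secreted protease gene HTRA1 by 0.66 and 0.89. IGFBP3, which binds insulin-like growth factors, fell by 0.94 and 0.71 and the membrane skeleton gene EPB41L3 fell further (-2.78, SE 0.28, and -3.24, SE 0.28). With shLCN2_1 limma called 56 genes higher and 65 lower (2010 at an unadjusted p under 0.05), with shLCN2_2 20 and 55 (2013). Of these 4 were higher and 2 lower with both, beside 0.0778 and 0.248 for independent lists. The mean of 0.01 in simulations with no group changed does not measure what the shared controls add. Across genes the hairpins' fold changes had a Pearson correlation of 0.528 and a covariance of 0.0727, beside 0.498 and 0.0335 simulated, and 0.352 and 0.0346 with the GC trend removed, beside 0.5001 and 0.0219. Part of this may come from the shared controls. With the replicate number as a block, limma called 47 genes with shLCN2_1, 1 with shLCN2_2 and 0 with both. Other settings called more with shLCN2_1 and shLCN2_2: 297 and 188 by edgeR, 488 and 350 by DESeq2, and 1347 and 1069 by limma with the GC trend removed.

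With shLCN2_1, keratin 7 (KRT7, 2.09, SE 0.20) and desmoplakin (DSP, 0.63) rose among epithelial genes (2 higher and 0 lower of 14, 3 and 0 adjusted over the list alone, median 0.48, adjusted p = 0.00278, 0.281 with an estimated correlation). IFITM1 rose (1.23) among interferon-stimulated genes (1 and 0 of 31, 4 and 0 adjusted over the list alone, median 0.25, adjusted p = 1.81e-05, 0.0849 with an estimated correlation). Hypoxia response genes rose (2 higher and 0 lower of 33, 4 and 0 adjusted over the list alone). Their median was 0.24 (adjusted p = 1.24e-06, 0.0849 with an estimated correlation), and they were led by NDRG1 and VEGFA (0.58). The interleukin genes IL1A (-1.39) and IL6 (-0.86) fell (NF-kB list, 0 and 2, 5 and 4 adjusted over the list alone), as did NQO1 (-1.004), EREG (-1.05) and HLA-DRA (-0.85). Mitochondrially encoded transcripts were lower as a list with no single call (median -0.34, adjusted p = 1.81e-05, 0.464 with an estimated correlation). Ribosomal protein genes were lower (0 and 1 of 30, the same adjusted over the list alone, median -0.09, adjusted p = 0.00694, 0.464 with an estimated correlation), with RPS20 at -0.68, but not without shLCN2_1 replicate 1 (0.393). ATF4 response genes were higher (1 and 0 of 21, 3 and 0 adjusted over the list alone, median 0.10, adjusted p = 0.0468, 0.281 with an estimated correlation), a call lost without any of 5 libraries (0.0515 to 0.0808). Fold changes followed GC content (Spearman correlation 0.509 across genes), and with that trend removed the epithelial and ATF4 lists were not called (0.103 and 0.420).

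With shLCN2_2, the class II genes HLA-DRA (0.73) and HLA-DRB1 (1.14) rose among antigen presentation genes (3 higher and 0 lower of 22, 4 and 1 adjusted over the list alone). Their median was 0.28 (adjusted p = 0.00307, 0.389 with an estimated correlation). The inflammatory genes CCL2 (1.14) and PTGS2 (0.98) rose, OASL fell by 1.43, cyclin A2 (CCNA2) by 0.99 and the iron transporter gene SLC11A2 by 1.16. Interferon-stimulated genes fell (0 and 1 of 31, 0 and 8 adjusted over the list alone). Their median was -0.18 (adjusted p = 0.00399, 0.253 with an estimated correlation). Hypoxia genes rose (1 and 0 of 33, 2 and 1 adjusted over the list alone). Their median was 0.20 (adjusted p = 0.00399, 0.253 with an estimated correlation). Cell cycle genes fell (0 and 1 of 34, the same adjusted over the list alone). Their median was -0.15 (adjusted p = 0.00436, 0.271 with an estimated correlation). Epithelial (0 and 0 of 14, 2 and 0 adjusted over the list alone, adjusted p = 0.0165, 0.271 with an estimated correlation) and mesenchymal genes (0 and 0 of 19, 1 and 0 adjusted over the list alone, adjusted p = 0.0165, 0.253 with an estimated correlation) were both higher with a median of 0.27. Fold changes followed GC content here too (Spearman correlation 0.592 across genes), and with the trend removed the epithelial list was not called (0.283). The hairpins differed from each other in interferon-stimulated genes, which were higher with shLCN2_1 (8 higher and 0 lower of 31, 15 and 0 adjusted over the list alone, median difference 0.49, adjusted p = 2.72e-11, 0.0376 with an estimated correlation). Mitochondrially encoded transcripts were lower with shLCN2_1 (0 and 0 of 13, 0 and 6 adjusted over the list alone, -0.40, adjusted p = 1.01e-07, 0.611 with an estimated correlation). NRF2 genes (0 and 2 of 20, 0 and 5 adjusted over the list alone, -0.10, adjusted p = 0.00939, 0.253 with an estimated correlation) and ribosomal protein genes (0 and 1 of 30, the same adjusted over the list alone, -0.10, adjusted p = 0.0182, 0.791 with an estimated correlation) were lower too. Of 387 genes that differed between the hairpins, SPOCK1 (2.61), COL6A3 (2.64) and CXCL11 (2.57) were higher with shLCN2_1 and the protease gene MMP3 with shLCN2_2 (-2.80); all but MMP3 lost the call without any 1 hairpin library (adjusted p up to 0.126).

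For the mean of the hairpins in MDA231, limma called 14 genes higher and 12 lower (1958 at an unadjusted p under 0.05; 58 and 41 by edgeR, 156 and 148 by DESeq2), NDRG1 among the higher (0.87). Hypoxia genes rose (1 and 0, 7 and 0 adjusted over the list alone). Their median was 0.21 (adjusted p = 5.79e-06, 0.175 with an estimated correlation). Epithelial genes were higher (3 and 0 adjusted over the list alone, median 0.33, adjusted p = 0.000574, 0.245 with an estimated correlation). Cell cycle genes were lower (0 and 1 adjusted over the list alone, median -0.13, adjusted p = 0.00891, 0.281 with an estimated correlation). Antigen presentation (median 0.13, adjusted p = 0.0126, 0.592 with an estimated correlation), mesenchymal (median 0.20, adjusted p = 0.0334, 0.245 with an estimated correlation) and ATF4 genes (median 0.07, adjusted p = 0.0334, 0.245 with an estimated correlation) were higher as lists with no single call. They were not called with the GC trend removed (0.157, 0.114 and 0.436), and the ATF4 list was also not called without either parental library (0.0783 and 0.0777). No call was made for interferon-stimulated genes (median -0.04, opposite in sign to the direction of the test, adjusted p = 0.761) or iron handling (0.197, and 0.0293 with the GC trend removed). Whether the MDA231 knockdown calls rest on single libraries cannot be told from fits with 1 library left out. A fit without a LeptoM library has fewer degrees of freedom, and leaves 1 library in a group. Calls rose without either parental library, which enters these contrasts only through the shared spread. Without either shCTL library limma called 0 genes with either hairpin. Of the genes named for shLCN2_1, shLCN2_2 and the mean, all 15, 12 and 6 lost their calls (adjusted p up to 0.444, 0.442 and 0.911). Reads thinned to equal depth ended the calls of 7, 2 and 5 of them (up to 0.130, 0.0766 and 0.0979). With the GC trend removed limma called 653 genes higher and 694 lower with shLCN2_1, 420 and 649 with shLCN2_2, and 333 and 408 for the mean.

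In MDA231 LCN2 was close to the limit of detection, and its falls with shLCN2_1 and shLCN2_2 did not pass limma's test (adjusted p = 0.299 and 0.226). Changes shared with that line therefore need not reflect a loss of LCN2. Comparing the knockdown across lines, the cystatin gene CST4 rose by 1.81 in PC9 and 1.48 in MDA231 for the mean of the hairpins and the secreted protein gene SCUBE3 by 1.62 and 1.02. CHRAC1 fell by 0.33 and 0.50, LEPREL1 by 0.26 and 0.54 and NQO1 by 0.36 and 0.63. CST4 in PC9 was at 30.2 with shCTL, 29.9 with shLCN2_1 and 425 with shLCN2_2, so its mean reflects 1 hairpin. In all 5 genes were called higher and 3 lower in both lines (1.51 and 1.15 for independent lists, Fisher's exact test, two-sided, p = 0.0126 and 0.0887). The number was between 0 and 62 together with single libraries left out and 187 with the GC trend removed. By the test of the difference, AKR1C1 (-1.28 in PC9 and 1.47 in MDA231, adjusted p of the difference 0.0184) and OASL (0.56 and -1.43, 0.0207) differed between the lines with shLCN2_2. KRT7 (-1.11 and 2.09) and VEGFA (-0.83, or -0.39 with the GC trend removed, and 0.58) differed with shLCN2_1 (0.0107 for both). Across genes the fold changes of the lines had a Pearson correlation of -0.247, and of 0.115 with the GC trend removed.

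Whether the knockdown returned genes toward their parental level was examined across genes. Simulated correlations are set by the shared libraries alone, so the covariances are the closer comparison. In PC9 the fold changes of the mean of the hairpins and of LeptoM shCTL against parental had a Pearson correlation of -0.113 (Spearman -0.168) and a covariance of -0.0446, beside -0.577 and -0.0260 simulated for unchanged groups that share the shCTL libraries. After removal of the GC trend the covariance was -0.0156, beside -0.0233 simulated. In MDA231 the correlation was 0.346 (Spearman 0.440) and the covariance 0.116, beside -0.578 and -0.0335 simulated, and 0.222 and 0.0565 with the GC trend removed.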

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

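The tests that weigh explanations below were chosen after the results were seen, including those with the GC trend removed and with reads thinned. Differences between the lines were tested directly, with an adjustment over 38 tests for lists and over 13388 genes for genes. The lists below are those whose difference passed. The genes are those named in the text that were also called in opposite directions in the lines.

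Between LeptoM shCTL and parental cells, the lines differed most in mesenchymal genes such as VIM and COL5A1, whose median difference, PC9 minus MDA231, was -1.63 (adjusted p = 7.96e-05). The same difference was 0.61 for NRF2 antioxidant genes (3.59e-05), 0.56 for ribosomal protein genes (1.44e-06), 0.54 for cholesterol synthesis (0.0282), 0.50 for the ATF4 response (0.0142) and 0.21 for respiration and iron-sulfur proteins (0.0371). It was -0.81 for mitochondrially encoded transcripts (0.00153), -0.73 for antigen presentation (0.00636) and -0.35 for hypoxia response genes (0.0282), the last not called with the GC trend removed (0.132). For the mean of the hairpins the difference was 0.69 for interferon-stimulated genes (2.47e-06) and 0.30 for mitochondrially encoded transcripts (0.0063). It was -0.51 for epithelial genes (0.000535), -0.51 for NRF2 genes (0.000993), -0.44 for the ATF4 response (1.05e-05), -0.42 for NF-kB genes (0.000535), -0.36 for MAPK output (0.00568), -0.24 for ribosomal protein genes (5.50e-05) and -0.15 for hypoxia response genes (0.0138). With the GC trend removed the hypoxia, MAPK and mitochondrially encoded differences for the hairpins were not called (0.139, 0.179 and 0.179). The others stayed called but were smaller. They were -0.15 for epithelial genes, -0.24 for NRF2, -0.21 for ATF4, -0.28 for NF-kB, -0.18 for ribosomal protein and 0.53 for interferon-stimulated genes.

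Single genes whose change between LeptoM shCTL and parental cells was lower in PC9 than in MDA231, by the difference of log2 fold changes, were the receptor GPR176 (-10.11), SPOCK1 (-8.63), MAGEA6 (-8.11), COL5A1 (-7.16), ACSS3 (-6.48), VIM (-4.53), COL6A1 (-4.35), AC002480.3 (-3.84), ICAM1 (-3.33), ARHGAP31 (-3.32), the complement protease C1R (-3.28), HLA-B (-3.22), VEGFA (-1.92), SDHA (-1.33) and LIF (-1.09), with adjusted p of at most 0.00846. The sizes for GPR176, MAGEA6 and ACSS3 depend on the 1 added before the logarithm, since these had 5 and 3 reads over both MDA231 parental libraries and 0 in PC9 LeptoM shCTL cells. Genes whose change was higher in PC9 were SLC7A11-AS1 (9.83), ATF3 (3.28), IGFBP3 (3.19), NQO1 (2.75), ASNS (2.66), CYBRD1 (2.17), SLC7A11 (1.88), PSAT1 (1.81), RPS27 (1.59), RPL32 (1.57), RPS18 (1.26), FTL (0.93) and RPL7 (0.79), with adjusted p of at most 0.00428. With shLCN2_1 the lines differed in KRT7 (-3.21), LCP1 (3.18) and VEGFA (-1.42), each with an adjusted p of 0.0107, and with shLCN2_2 in AKR1C1 (-2.76, 0.0184), OASL (1.99, 0.0207) and IGFBP3 (1.18, 0.0295). Outside the gene values, the reads assigned to no single place came to 42.4% of gene reads in PC9 parental replicate 2, a signal in the counts that was not used here.

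The rise of interferon-stimulated genes such as OAS2 and IFI6 with the PC9 hairpins may be a response to the loss of LCN2, an effect of the GC trend or a reaction to the hairpins themselves. It remained with the GC trend removed (median 0.51, adjusted p = 1.53e-09) and without either shCTL library (1.38e-08 and 6.60e-10), so neither the trend nor 1 control library accounts for it, although with the trend and all libraries kept the list had an adjusted p = 0.116 with an estimated correlation. In MDA231 the list was higher with shLCN2_1 as well (median 0.25, adjusted p = 1.81e-05, 0.0849 with an estimated correlation), so a response to that hairpin in both lines stays open. It was lower there with shLCN2_2 (-0.18, adjusted p = 0.00399, 0.253 with an estimated correlation), which argues against a response to shLCN2_2 shared by both lines. A reaction to shLCN2_2 in PC9 alone cannot be excluded by values from MDA231. Whether the rise follows the amount of LCN2 lost was not decided: shLCN2_1, which lowered LCN2 more, differed from shLCN2_2 by -0.32 (adjusted p = 0.244, 0.678 with an estimated correlation), and by -0.33 with the GC trend removed (0.0191). What remains could be an effect of LCN2 loss or of each vector, and a rescue with hairpin-resistant LCN2 would separate them.

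The higher mitochondrially encoded transcripts, such as MT-ND5, in MDA231 LeptoM cells might reflect the cells, the lower depth of the parental libraries or their GC trend. The median was 0.94 with the GC trend removed (camera adjusted p = 5.81e-06), so that trend does not account for it. With all reads and the trend kept, however, the adjusted p was 0.525 with an estimated correlation. With reads thinned to equal depth the median was 0.78 (0.000146). Thinning leaves the expected ratio of well-counted genes unchanged, and MT-ND5 had 6930 parental reads. The thinned fit therefore could not decide whether depth plays a part. A separate batch of parental libraries was not decided, because the deepest held 11.6 M gene reads and the shallowest LeptoM library 41.8 M, so no parental library matched the LeptoM libraries and a batch cannot be told apart from the group.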

How the results depend on the processing

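Of the results compared under the planned settings, leaving out libraries aside, 211 stayed the same, 49 moved and 3 became weaker; the cause was not tested unless said. A required log2 fold change of at least 1 lowers counts by construction: in PC9 to 2098 for LeptoM shCTL against parental, 1867 with shLCN2_1, 502 with shLCN2_2, 421 for the mean, 2350 between hairpins and 110 with both hairpins, in MDA231 to 2393, 64, 30, 16, 122 and 2, and across lines to 251 for LeptoM shCTL against parental and 2 for the mean of the hairpins.

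In MDA231 other tools called more genes in the hairpin contrasts, and fewer in LeptoM shCTL against parental (6701 by edgeR and 6325 by DESeq2, beside 7001). DESeq2 called 488 with shLCN2_1, 350 with shLCN2_2, 304 for the mean, 819 between hairpins and 52 with both, and 71 for the mean in both lines, and gave LCN2 1.496 in LeptoM shCTL against parental (adjusted p = 0.258). edgeR called 297, 188, 99, 687 and 31, and 22 in both lines, with LCN2 at 1.48 (0.0632). Fitting only the groups compared gave 4382 for LeptoM shCTL against parental, 384, 204, 250 for the mean, 31 with both hairpins and 52 in both lines, with LCN2 at 1.49 (0.102), and in PC9 8045 with shLCN2_2 and 1498 with both hairpins.

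With the GC trend removed PC9 calls were 3757 with shLCN2_1 and 5100 between hairpins, and the correlation of the knockdown with LeptoM shCTL against parental was -0.0446. MDA231 calls were 1347 with shLCN2_1, 1069 with shLCN2_2, 741 for the mean, 2632 between hairpins and 179 with both, the correlation 0.222, and 187 were shared by the lines. With the trend removed 4 genes changed sign with shLCN2_1 in PC9: EPHA2 from -0.95 to 0.0860 (adjusted p = 0.237), SH2D5 from -1.03 to 0.38 (0.233), CFD from -1.29 to 0.40 (0.460) and FOXC1 from -0.31 to 0.0156 (0.917).

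A block for replicate number lowered MDA231 calls to 47 with shLCN2_1, 1 with shLCN2_2, 0 for the mean (limma, 1835 at an unadjusted p under 0.05), 178 between hairpins, 0 with both hairpins and 0 for the mean in both lines. The labels give the replicates only a number. Deviations of equal number had Pearson correlations across genes of -0.0242 to 0.0831 in PC9 and -0.589 to 0.446 in MDA231. Between the MDA231 parental, shCTL and shLCN2_2 groups they were 0.364 to 0.446, while shLCN2_1 ran against each of these groups (-0.589 to -0.408). A block by number therefore does not follow this shared variation, and its MDA231 counts are to be read with that limit. With the block and the GC trend removed together PC9 calls were 3458 with shLCN2_1 and 4826 between hairpins (correlation -0.0446), and MDA231 calls 1230, 966, 589, 2482 and 162 (correlation 0.222), with 153 in both lines and LCN2 at 1.20 (0.0538). The same 4 genes changed sign with the block: EPHA2 0.0860 (0.282), SH2D5 0.38 (0.272), CFD 0.40 (0.460) and FOXC1 0.0156 (0.915).

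Reads thinned to equal depth gave 52 MDA231 calls with shLCN2_1, 9 for the mean, 211 between hairpins, 2 with both and 2 in both lines, a correlation of 0.208 and LCN2 at 0.97 (0.508). Without a filter the PC9 correlation was -0.181 and the MDA231 correlation 0.179, with 11 calls for the MDA231 mean and 0 in both lines. A filter of 50 gave 0.436 in MDA231 and 4 in both lines, upper-quartile scaling 5 in both lines, and a pseudocount of 8 11 with both MDA231 hairpins. With an estimated correlation 1 of 57 gene list calls was kept, not counting the lists tested between the hairpins.

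With 1 library left out at a time, PC9 counts ran from 4161 to 8889 for LeptoM shCTL against parental (7138 with all), 3866 to 8173 with shLCN2_1 (6910), 361 to 5469 with shLCN2_2 (3053), 120 to 6453 for the mean (4372), 5817 to 9453 between hairpins (8529) and 119 to 1690 with both (847). The PC9 correlation ran from -0.167 to -0.0519 (-0.113), and LCN2 from 1.11 to 1.25 in LeptoM shCTL against parental, -3.81 to -2.84 with shLCN2_1 and -1.42 to -1.23 with shLCN2_2. MDA231 counts ran from 3486 to 9081 (7001), 0 to 674 (121), 0 to 366 (75), 0 to 256 (26), 8 to 1225 (387) and 0 to 61 (6), the correlation from 0.221 to 0.425 (0.346), and LCN2 from 0.86 to 2.12, -1.51 to -1.04 and -1.86 to -1.38. Counts shared by the lines ran from 924 to 2467 (1866) and 0 to 62 (8), and gene list calls from 55 to 62 (57).

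Of the results for single genes and lists, 3669 stayed the same under planned settings and 132 became weaker, 978 and 87 under added ones, and 2447 and 425 with libraries left out.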

Other observations

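The lists in this part were put together after the values were seen, so their tests, adjusted over 16, describe genes already known to be high.

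Mucosal secretory genes, which encode the mucins and antimicrobial proteins of airway and gut surfaces, rose in PC9 LeptoM cells. Of 16 tested, 15 were higher and 1 lower (median 2.52, camera adjusted p = 1.88e-09; 0.0712 with an estimated correlation), among them MUC20 (3.30), CEACAM6 (2.93), CEACAM1 (2.68), MUC16 (2.36), BPIFB1 (2.26), TFF1 (2.09) and SLPI (1.12), while WFDC2 fell by 0.69. SCGB1A1 went from 2.98 to 45.3. The median was 2.50 with the GC trend removed (adjusted p = 9.85e-09). With shLCN2_2 5 rose and 0 fell (median 0.36, adjusted p = 0.0115; 0.171 with an estimated correlation), and with shLCN2_1 4 rose and 7 fell (median -0.14, adjusted p = 0.588). After removal of the GC trend 2 members were called higher with shLCN2_1, WFDC2 and BPIFA1, and 2 lower, CEACAM1 and CEACAM6 (median 0.04, adjusted p = 0.904). In MDA231 all 4 measured members were called higher in LeptoM shCTL cells (median 4.04, adjusted p = 0.0115; 0.171 with an estimated correlation), but 3 had parental means under 3 reads per library, among them MUC5B with 0 (9.79 in LeptoM cells) and SLPI (1.49 to 22.7). With these set to 3 reads the median was 2.71. With shLCN2_1 in MDA231 the list was higher with no single call (median 0.97, camera adjusted p = 0.0204, 0.193 with an estimated correlation). With the GC trend removed it was not called (0.0709), although the median was 1.02.

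Cancer-testis genes, normally restricted to the germline, rose in MDA231 LeptoM cells, with 7 higher and 1 lower of 10 (median 5.91, adjusted p = 0.00126; 0.135 with an estimated correlation), and the median was 5.86 with the GC trend removed (0.0240). In parental cells 4 members had 0 reads and 2 more were under 3 reads per library, and with these set to 3 reads the median was 3.01. With shLCN2_1 in MDA231 they were lower as a list with no single call (median -0.44, camera adjusted p = 0.0204, 0.171 with an estimated correlation). With the GC trend removed they were not called (0.0929), although the median was -0.65. In PC9 1 was higher and 2 lower of 6 (median -0.23, adjusted p = 0.531): MAGEA1 rose by 6.43, from 19.1 to 1707, and MAGEA3 fell by 1.27. Reads of the MAGEA and SSX families fall on near-identical copies, so the member within a family is uncertain.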
